A study of Mus musculus with 12 samples.

How the data were processed

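The study profiled sorted tuft cells of the small intestine of untreated mice by bulk RNA sequencing. Per the labels' protocols, full-length cDNA was amplified with a SMART-Seq v4 kit, libraries were made by Nextera XT tagmentation and single reads were taken on an Illumina HiSeq instrument; the protocol does not mark strand as far as the labels say, so overlapping and antisense genes cannot be told apart. Per the submitters' processing notes, reads were quantified with kallisto against GRCm39 (mm39); its version, the annotation, the offset and the tool that made the log values are not given in the sources used here. The authors deposited 1 table of log2 CPM for 12614 genes in 12 libraries with 2 decimals, together with their group means and log2 fold changes, which the values recomputed here met within 0.0075 and 0.01. All libraries share the lowest value, -1.33, equal to 0.398 CPM, which stands for an offset and not for a measured level. No gene lies above it in fewer than 4 libraries, so the authors' table was filtered before it was deposited. Turned back to a linear scale, the values sum to 852.1 in the lowest library and 1474.6 in the highest, in units of 1e3 CPM, so the authors rescaled library sizes beyond plain CPM. Estimated counts of kallisto need not be whole, and reads that match several transcripts are shared among them.

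Library size was read from the spacing of the low values. In Balb replicate 2, 1 read was worth 0.361 CPM, and less in all others. This gives 2.77e6 to 6.83e6 reads as the library size in the denominator, which was rescaled and is not depth itself. Between 32.6% and 41.4% of low values were whole reads within a tolerance of 0.1, so reads could not be recovered and no count model was run. On 200 simulated changes among 12614 genes, the fit for Balb minus B6 recovered 84.8% of changes of 4 on the log2 scale, 37.3% of 2 and 6% of 1, with 7 false calls; congenic minus B6 recovered 81.8%, 37.3% and 4.5% with 4 false calls, and congenic minus Balb 81.8%, 41.8% and 9% with 8. Changes of 1 or less were therefore mostly not detectable at this depth and number of libraries.

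Groups came from the genotype label. Replicate numbers were given in accession order and pair nothing. Pair correlations of libraries across genes were 0.787 to 0.896 within groups and 0.772 to 0.881 between groups, and no 2 libraries held identical values. Of the gene names, 16 have been turned into dates and were kept as they stand but never named, and 2 share a name. Of all symbols, 11854 (94.0%) were found in GENCODE M21, whose genome build, GRCm38, differs from the authors'; it was used only for chromosomes, gene order and transcript sequences, and no coordinates are given. Pou2af2 was matched through its older symbol.

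The design, the gene lists, the rule for named genes and the other settings listed below, except where said, were fixed before the data were examined. Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values, in 1 fit of all 12 libraries with a mean per group, a trended prior variance (prior degrees of freedom 7.02) and 3 contrasts, each with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The design foresaw a pseudocount of 1 on CPM values; the table already held log2 values, so the branch written for that case was used. A filter of log2 CPM of at least 0 in at least 4 libraries removed 0 genes. Fold changes are on the scale of the offset values and understate changes of low genes; no fold is given for a gene with a whole group at the lowest value. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry (in 1 direction and, chosen after seeing the data, in either direction), adjusted over the 25 lists of 29 with at least 3 measured genes. The lists were tuft identity, neuronal-type and immune-type tuft, chemosensing, eicosanoid, cholinergic, type 2 cytokine, type 2 response, interferon, MHC class I and class II, dissociation stress, unfolded protein, mitochondrial, known strain differences, the neighbourhood of Pou2af2, Pou2af2 with its partners, and markers of enterocyte, goblet, Paneth, enteroendocrine, stem, proliferation, T cell, B cell, myeloid, eosinophil, stroma and red blood cells. Several lists share genes; Itln1, for example, is on the Paneth and the type 2 response list.

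Genes were named by rule: Pou2af2 and its partners; per contrast the 6 largest rises and falls among called genes with a mean of at least 10 CPM in the higher group and groups that do not overlap, without predicted, clone, pseudogene or immune-receptor segment names; up to 3 called members per list with the smallest p; and up to 2 abundant members of lists with no called member. A gene that the rule reaches is not reported here. Clone-type names such as those beginning with AK or RP were treated as clone names. Lyz1, Trpm5, Gpr35, Sct, Defa20, Defa22, Rps2 and Hist1h2al in Balb minus B6 were chosen after their values were seen. So were H2-D1 in both comparisons with B6 and the genes of the closing section that the rule does not reach. Examples of partial matches between transcripts were chosen after the matches were seen. Small comparisons used two-sided exact permutation tests over 70 assignments. The place of the congenic strain was taken as its difference from B6 divided by the difference of Balb from B6. Chance values for comparisons that share libraries came from 50 simulations of unchanged groups.

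Near-identical copies were found by aligning the longest transcript of each called gene, and of 1000 sampled genes not called, to all GENCODE transcripts with BLAST 2.17.0, at 90% identity over 50% of the shorter transcript. Each gene with a copy in the table was then replaced by the log2 sum over gene and copies and the fit repeated. For congenic minus Balb only 10 of the 18 called genes had a transcript, so the share of genes with a copy is not given there. Other settings were pseudocounts of 0.25, 4 and 1 CPM, a mean of at least 10 CPM, median-ratio and quantile rescaling, a fit of only the groups compared, no variance trend, a robust prior, quality weights, a minimum fold, and each library left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 made the summaries and figures.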

Results

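Tuft cells are rare chemosensory cells of the gut epithelium that sense luminal metabolites and release interleukin 25. They were sorted from the small intestine of untreated mice as live cells without CD45 and with EPCAM, CD25 and Siglec-F. Their messenger RNA was measured in bulk in 12 libraries. The libraries form 3 groups of 4, from the inbred strains C57BL/6J (B6) and Balb/cJ (Balb) and from a congenic strain that the labels number as strain 3 (congenic). The title of the series names Pou2af2, a coactivator of the tuft cell transcription factor POU2F3, and genetic mapping. The comparisons therefore ask how the tuft cells of the parental strains differ and where the congenic strain stands between them. The background and the donor interval of the congenic strain are not given in the sources used here. The table holds log2 CPM, read counts scaled to a common library size, for 12614 genes. The rescaled library size, read from the spacing of the table's low values, was lowest in Balb replicate 2 (2.77e6 reads) and highest in B6 replicate 2 (6.83e6 reads). This size is not depth itself. Values below are group means ± SD over n = 4 libraries on the log2 CPM scale. The labels do not say that the libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical.

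Pou2af2, listed in the table under its older symbol 1810046K07Rik, stood at 5.14 ± 0.91 in B6, 1.05 ± 2.80 in Balb and 4.18 ± 0.81 in the congenic strain. In Balb it split within the group, with 4.09 in replicate 1, 2.77 in replicate 4 and the lowest value of the table, -1.33, in replicates 2 and 3. The Balb mean fell by 4.09 on the log2 scale against B6 (SE 1.02, limma adjusted p = 0.0475), but the groups overlapped. An exact permutation test of the same 4 and 4 libraries gave p = 0.0571, or 0.257 after adjustment over the 6 such tests. The smallest exact permutation p possible is 0.0286, so 1 comparison alone could not pass that adjustment. The limma call held in 2 of the 12 fits with 1 library left out. Its limma adjusted p reached 0.158 without B6 replicate 1, 0.151 without B6 replicate 2, 0.128 without Balb replicate 3 and 0.125 without Balb replicate 2. The congenic strain did not differ detectably from B6 in Pou2af2 (log2 difference -0.96, limma adjusted p = 0.876) or from Balb (3.13, limma adjusted p = 0.618). Pou2f3, the transcription factor that tuft cells need to form, stood at 7.32 ± 0.35 in B6, 6.88 ± 0.75 in Balb and 7.20 ± 0.55 in the congenic strain. Its limma adjusted p were 0.699 for Balb minus B6, 0.955 for congenic minus B6 and 0.967 for congenic minus Balb. The related coactivators Pou2af1 and Pou2af3 were not analysed here.

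**Figure D1:**
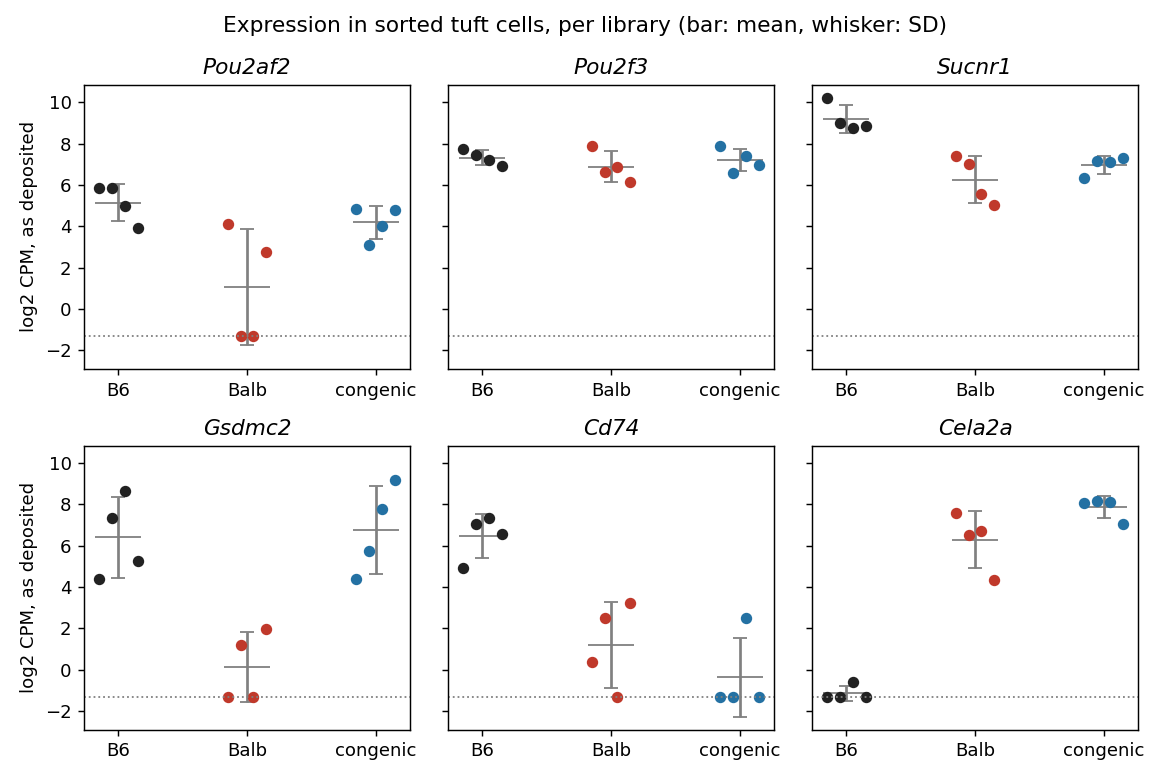
Expression in each library (points, log2 CPM) of Pou2af2, Pou2f3, Sucnr1, Gsdmc2, Cd74 and Cela2a in the 3 groups of 4 libraries. Bars mark group means, whiskers the SD and the dotted line the lowest value of the table, -1.33, at which Pou2af2 stood in 2 of the 4 Balb libraries.

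Between the parental strains, Balb libraries carried more of 8 Paneth transcripts, markers of the defensin-secreting cells of the crypt base, and fewer of Sucnr1, Calhm3, Cd74 and H2-Ab1 and of the near-identical gasdermin genes Gsdmc3 and Gsdmc4. The largest rise was that of the alpha-defensin-related gene Defa-rs7 (10.09 ± 1.39 against -0.61 ± 1.18; log2 fold change 10.70, SE 0.74, limma adjusted p = 3.42e-07). The elastase gene Cela2a rose from -1.15 ± 0.37 to 6.28 ± 1.37 (log2 fold change 7.43, SE 0.55, limma adjusted p = 8.49e-07), and Ceacam10 rose by 6.07 (limma adjusted p = 0.000903). Muc2, the gel-forming mucin of goblet cells, rose by 6.86 (SE 1.58, limma adjusted p = 0.0318). Mptx1, a mucosal pentraxin, stood at 5.75 ± 3.20 in Balb and at the table's lowest value in all B6 libraries (limma adjusted p = 0.0272). St3gal4, a sialyltransferase gene, fell from 8.15 ± 0.47 to -0.62 ± 1.42 (log2 fold change -8.77, SE 1.03, limma adjusted p = 0.000138). The gasdermin gene Gsdmc4 fell by 7.99 (SE 1.25, limma adjusted p = 0.00159), and Gsdmc3 was at the lowest value in all Balb libraries against 5.18 ± 1.89 in B6 (limma adjusted p = 0.00152). The small proline-rich protein genes Sprr2a2 and Sprr2a1 fell by 7.22 and 6.57 (limma adjusted p = 0.000574 and 0.000139). Gvin1, a giant interferon-inducible GTPase, fell by 7.10 (SE 0.73, limma adjusted p = 3.57e-05). In all, limma called 265 of 12614 genes, 128 higher and 137 lower in Balb, of which 56 carry predicted, clone or pseudogene names. An unadjusted p under 0.05 was found for 1525 genes. Muc2 and Mptx1 were called in 5 and 6 of the 12 fits with 1 library left out, with limma adjusted p up to 0.103 without B6 replicate 1 and 0.094 without Balb replicate 4. The count of called genes was 174 without B6 replicate 1.

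In the chemosensing list, 2 of 15 genes, Sucnr1 and Calhm3, fell in Balb. Sucnr1, the succinate receptor of tuft cells, fell from 9.20 ± 0.68 in B6 to 6.25 ± 1.14 in Balb (log2 fold change -2.95, SE 0.46, limma adjusted p = 0.0015). Calhm3, a subunit of the taste-cell ATP channel, stood at 4.11 ± 1.04 in B6 and at the lowest value in all Balb libraries (limma adjusted p = 0.000599). These were the 2 falls over all genes among the 15 chemosensing genes, of which 11 were lower, 4 higher and 4 fell adjusted over the list alone (camera adjusted p = 0.0111). With an estimated correlation the list had a camera adjusted p = 0.461. The channel gene Trpm5 differed by -0.50 (limma adjusted p = 0.65) and the receptor gene Gpr35 by 1.05 (limma adjusted p = 0.555). Of 45 tuft identity genes, 40 were lower in Balb, with a median log2 fold change of -0.61 (camera adjusted p = 1.41e-07). That list had an adjusted p = 0.464 by camera with an estimated correlation. None of its genes fell over all genes, and Ascl2, a transcription factor also of crypt stem cells, rose by 1.77 (limma adjusted p = 0.0333). Adjusted over the list alone, 1 rose and 2 fell. The immune-type tuft list was lower in 13 of 13 genes, with 2 falls adjusted over the list alone and none over all genes (camera adjusted p = 0.000828). Its camera adjusted p was also 0.464 with an estimated correlation, and its most abundant members Tm4sf4 and Rac2 differed by -0.80 and -0.70. In the eicosanoid synthesis list 11 of 16 genes were lower and none passed by either adjustment (camera adjusted p = 0.0487). For eicosanoid genes the camera adjusted p was 0.299 with an estimated correlation. Without Balb replicate 4 the camera adjusted p rose to 0.154 for chemosensing and 0.0781 for the immune-type tuft list, and without B6 replicate 1 to 0.173 for eicosanoid synthesis. Ascl2 was called in 7 of 12 such fits, with limma adjusted p up to 0.0939 without B6 replicate 2.

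Of 14 Paneth genes 8 rose and 1 fell over all genes, and 11 rose and 1 fell adjusted over the list alone (camera adjusted p = 3.58e-11). With an estimated correlation the Paneth list had a camera adjusted p = 0.299. Among the rises were Defa17 (log2 fold change 4.92, SE 0.67, limma adjusted p = 0.000548), Defa3 (4.59, SE 0.71, limma adjusted p = 0.00143) and the lysozyme gene Lyz1 (4.69, limma adjusted p = 0.00362). The fall was that of Defa21 (-5.89, limma adjusted p = 7.63e-05), which turned to 1.65 and lost its call when summed with its near-identical copies (limma adjusted p = 0.306). Goblet genes were higher in 12 of 12, of which Muc2 passed over all genes and 9 rose adjusted over the list alone (camera adjusted p = 1.19e-08). For goblet genes the camera adjusted p was 0.299 with an estimated correlation. The goblet transcripts summed to 929.6 CPM in Balb replicate 3, inside the B6 range of 548 to 1289.8, and to 9538 to 15859 in the other Balb libraries (exact permutation p = 0.0857). The stem cell list was higher in 9 of 12 genes, with 1 rise by either adjustment, the ion transporter gene Slc12a2 (1.43, limma adjusted p = 0.0217). This list had a camera adjusted p of 0.0422, and of 0.308 with an estimated correlation. Gcg, the proglucagon gene, stood at 2.32 ± 0.80 in Balb and at the lowest value in all B6 libraries (limma adjusted p = 0.0141), 1 rise among 6 enteroendocrine genes by either adjustment. Sct, the secretin gene and the most abundant of the 6, stood at 7.22 ± 0.67 in Balb and 8.03 ± 0.69 in B6 (limma adjusted p = 0.374). The Paneth transcripts summed to 46954 CPM in Balb replicate 1 and 4443 to 5728 in the other Balb libraries, against 235 to 1078 in B6. Slc12a2 was called in 7 of 12 fits with 1 library left out (limma adjusted p = 0.0743 without Balb replicate 4), and the stem list in 6 (camera adjusted p = 0.111 without Balb replicate 1).

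Among antigen-presentation genes, 2 of class II and 1 of class I fell in Balb. A strain variant that keeps reads from the reference transcript could also lower these and other single genes, and was not told apart here. Cd74, the invariant chain of MHC class II, fell from 6.46 ± 1.07 to 1.19 ± 2.06 (log2 fold change -5.27, SE 1.06, limma adjusted p = 0.0124), and the class II chain gene H2-Ab1 fell by 4.36 (limma adjusted p = 0.0407). These were the 2 falls over all genes among the 5 measured class II genes, with 3 adjusted over the list alone (camera adjusted p = 0.00238). With an estimated correlation the class II list had a camera adjusted p = 0.299. Of 21 class I genes H2-K1 fell by 2.09 (limma adjusted p = 0.00734), with 2 falls adjusted over the list alone, while 9 were higher (camera adjusted p = 0.757). Summed with its near-identical copies, H2-K1 lost its call (-0.97, limma adjusted p = 0.275). Among these copies is the class I gene H2-D1, at 10.97 ± 0.66 in B6 against 7.86 ± 0.56 for H2-K1. H2-D1 differed by -0.90 alone, and the sum follows it. The lost call therefore does not decide about H2-K1 itself. Of 30 interferon-stimulated genes 24 were lower and none passed by either adjustment (camera adjusted p = 0.0343). The interferon list had a camera adjusted p = 0.688 with an estimated correlation. Cd2, a T cell adhesion receptor, was at the lowest value in all Balb libraries and at 1.38 ± 0.75 in B6 (limma adjusted p = 0.0476). It was the 1 fall by either adjustment in the T cell list, which was lower in 4 of 4 genes (camera adjusted p = 0.0375). For T cell genes the camera adjusted p was 0.308 with an estimated correlation. Of the 13 genes encoded by mitochondrial DNA 12 were higher, 1 of them rising adjusted over the list alone (camera adjusted p = 0.000828). That list had a camera adjusted p = 0.464 with an estimated correlation, and its member mt-Nd3 instead fell by 1.63 (limma adjusted p = 0.0124). Mitochondrial genes made up 45.64% of the summed CPM in Balb replicate 2 and 18.34% to 30.36% in the other 11 libraries. H2-Ab1 was called in 3 and Cd2 in 1 of 12 fits with 1 library left out (limma adjusted p up to 0.125 and 0.155, both without B6 replicate 2). The camera adjusted p rose to 0.46 for interferon without Balb replicate 4, 0.111 for T cells without Balb replicate 1 and 0.0735 for mitochondrial genes without Balb replicate 2.

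The other lists did not separate the parental strains by camera. The camera adjusted p were 0.124 for enteroendocrine, 0.149 for type 2 cytokine, 0.358 for myeloid, 0.363 each for cholinergic and dissociation stress, 0.477 for unfolded protein and 0.754 for neuronal-type tuft genes. They were 0.876 by camera for enterocyte, 0.894 for the neighbourhood of Pou2af2, 0.94 for type 2 response, 0.957 for known strain differences and 0.973 each for proliferation and stroma genes. In the type 2 response list Sprr2a1 and Sprr2a2 fell and 2 genes rose, among them the lectin gene Itln1 (3.71, limma adjusted p = 0.0264, but 0.102 without B6 replicate 1). The median of that list was 0.80 and its camera direction down, so these differed in sign. Of the 10 measured genes known to differ between the parental genomes none passed by either adjustment. Camera looks for a shift in 1 direction, while such genes can go either way. By fry's test of change in either direction, chosen after seeing the data, that list had a fry adjusted p of 0.00588. The same test gave fry adjusted p of 8.85e-07 for type 2 response, 3.12e-05 for class I and 0.0063 for enteroendocrine genes. It does not compare a list with other genes. Lists with fewer than 3 measured genes were not tested with camera or fry; those of B cell, eosinophil and red blood cell markers entered the marker sums. Siglecf, which belongs to the eosinophil list and to the gate, stood at 9.31 ± 0.43 in B6 and 8.23 ± 0.85 in Balb (limma adjusted p = 0.177). The eosinophil gene Cd300a stood at 2.22 ± 1.02 and 1.0 ± 0.38 (limma adjusted p = 0.672), the B cell gene Cd79b at 1.75 ± 1.71 and 2.34 ± 1.67 (limma adjusted p = 0.874) and the globin gene Hbb-bs at -0.23 ± 1.27 and 0.62 ± 2.40 (limma adjusted p = 0.84).

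**Figure D2:**
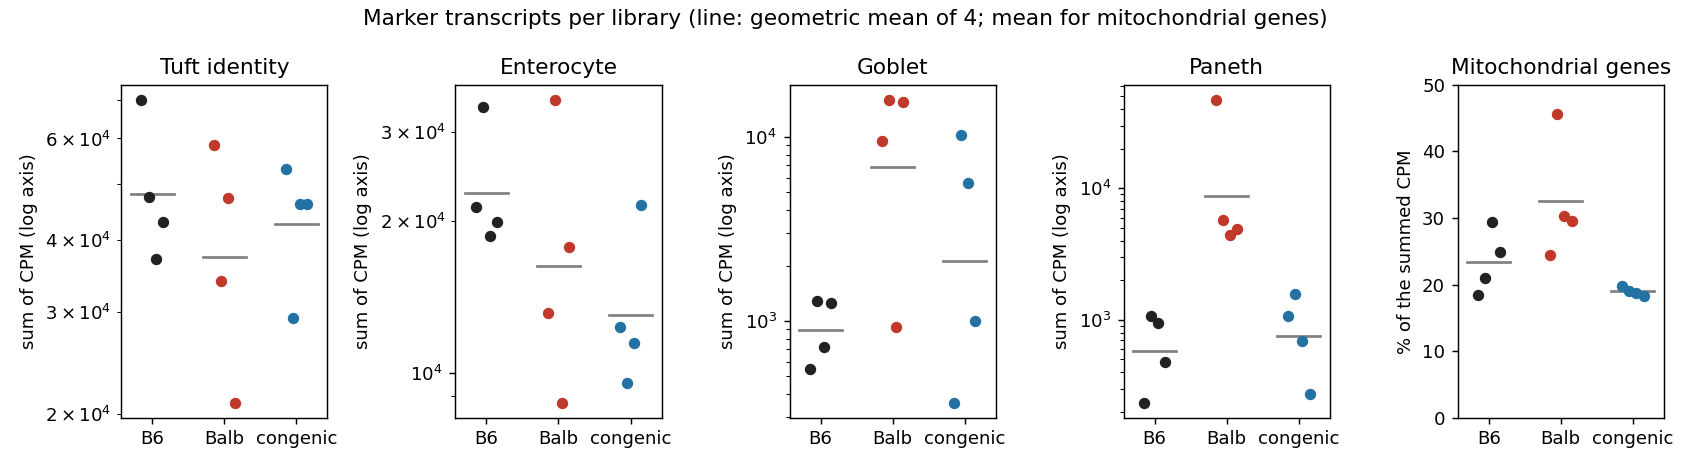
Summed CPM per library (points, log axis) of the tuft identity, enterocyte, goblet and Paneth lists, and percent of the summed CPM from genes of the mitochondrial genome, in the 3 groups of 4 libraries. Grey lines mark the geometric mean of 4 libraries (the mean for the mitochondrial percent); Paneth sums reach 46954 CPM in Balb replicate 1, and the mitochondrial share reaches 45.64% in Balb replicate 2.

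Between the congenic strain and B6, Cela2a, Defa-rs7 and Fah were among the genes that rose and Cd74, Gvin1 and Lect2 among those that fell. Cela2a rose to 7.85 ± 0.53 (SE 0.55 of the change, limma adjusted p = 5.79e-08) from -1.15 ± 0.37, and Defa-rs7 rose by 5.64 (SE 0.74, limma adjusted p = 0.000439). Fah, the last enzyme of tyrosine breakdown, rose from -1.03 ± 0.60 to 4.16 ± 0.62 (log2 fold change 5.19, SE 0.61, limma adjusted p = 0.000195). Cd74 fell to -0.38 ± 1.91 (log2 fold change -6.84, SE 1.06, limma adjusted p = 0.00198), and Gvin1 fell by 6.71 (SE 0.73, limma adjusted p = 8.78e-05). Lect2, a secreted chemotactic protein, fell from 6.49 ± 0.62 to 0.25 ± 2.03 (log2 fold change -6.24, SE 0.82, limma adjusted p = 0.000434). St3gal4 fell by 6.15 (SE 1.03, limma adjusted p = 0.00386), and Defa21 was at the lowest value in all congenic libraries (limma adjusted p = 2.65e-05). In all, limma called 160 genes, 70 higher and 90 lower in the congenic strain, of which 38 carry predicted, clone or pseudogene names. An unadjusted p under 0.05 was found for 1176 genes. The count of called genes was 104 without B6 replicate 2, 96 without congenic replicate 2 and 258 with quality weights per library.

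In the chemosensing list, 9 genes were lower and 6 higher in the congenic strain than in B6. Calhm3 (log2 fold change -4.84, limma adjusted p = 0.00221), Sucnr1 (-2.23, limma adjusted p = 0.0203) and Gnat3, the taste G protein gustducin (-1.92, limma adjusted p = 0.0498), were the 3 falls among 15 genes. Adjusted over the list alone 4 fell and 1 rose (camera adjusted p = 0.0365). With an estimated correlation chemosensing had a camera adjusted p = 0.53. Gnat3 was also the 1 fall by either adjustment among 45 tuft identity genes, of which 38 were lower (camera adjusted p = 9.27e-05). Of 13 immune-type tuft genes 12 were lower and none passed by either adjustment (camera adjusted p = 0.0239). Both tuft lists had a camera adjusted p = 0.639 with an estimated correlation. Goblet genes were higher in 11 of 12 and proliferation genes in 22 of 25, with none passing by either adjustment (camera adjusted p = 0.00416 and 0.0102). Their camera adjusted p were 0.53 and 0.639 with an estimated correlation. The goblet transcripts summed to 10259.6 and 5583 CPM in congenic replicates 2 and 3, and to 360 and 996 in replicates 1 and 4, against 548 to 1289.8 in B6 (exact permutation p = 0.371). Of 14 Paneth genes Defa21 fell over all genes, and 3 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.146). Sprr2a2 (-5.88, limma adjusted p = 0.00451) and Sprr2a1 (-5.75, limma adjusted p = 0.000515) fell, and the chaperone gene Calr rose by 0.93 (limma adjusted p = 0.0311). With 1 library left out the camera adjusted p rose to 0.203 for goblet and chemosensing and 0.131 for tuft identity, all without congenic replicate 2. It rose by camera to 0.373 for proliferation without B6 replicate 2 and 0.301 for immune-type tuft without B6 replicate 1. The limma adjusted p rose to 0.0775 for Sucnr1 without B6 replicate 1, 0.161 for Gnat3 without congenic replicate 1 and 0.134 for Calr without congenic replicate 4.

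Of 30 interferon-stimulated genes 29 were lower in the congenic strain than in B6, with a median log2 fold change of -1.12 and none passing by either adjustment (camera adjusted p = 3.69e-08). With an estimated correlation the interferon list had a camera adjusted p = 0.522. Its member Oas1a, an antiviral RNA sensor, stood at 6.34 ± 0.35 in the congenic strain and 7.46 ± 0.73 in B6. Cd74 and H2-Ab1 (-5.01, limma adjusted p = 0.0227) were the 2 falls among 5 class II genes, with 3 adjusted over the list alone (camera adjusted p = 0.000107). The class II list had a camera adjusted p = 0.472 with an estimated correlation. H2-K1 (-2.02, limma adjusted p = 0.013) and the light chain gene B2m (-0.93, limma adjusted p = 0.0337) were the 2 falls by either adjustment among 21 class I genes, of which 9 were higher (camera adjusted p = 0.146). The call of H2-K1 ended when it was summed with its near-identical copies (-0.65, limma adjusted p = 0.673). That sum follows the more abundant H2-D1 (-0.56 alone) and does not decide about H2-K1 itself. Mitochondrial genes were lower in 13 of 13, with mt-Nd3 the 1 fall by either adjustment (-2.49, limma adjusted p = 0.000434). That list had a camera adjusted p of 9.27e-05, and of 0.53 with an estimated correlation. With 1 library left out the limma adjusted p rose to 0.124 for B2m without B6 replicate 1, 0.0857 for H2-Ab1 without congenic replicate 4 and 0.0637 for H2-K1 without B6 replicate 2.

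Between the congenic strain and Balb, 6 genes of the Paneth list were lower in the congenic strain and the near-identical gasdermin genes Gsdmc2 and Gsdmc3 higher. Defa22 (log2 fold change -4.97, SE 0.62) and Defa20 (-4.80, SE 0.58) were lower in the congenic strain (limma adjusted p = 0.00188 for both). So were Defa17 (-4.81, limma adjusted p = 0.00433), Defa-rs7 (-5.06, limma adjusted p = 0.00729), Defa3 (-4.37, limma adjusted p = 0.0169) and Defa5 (-6.19, limma adjusted p = 0.03). Defa20 and Defa-rs7 are not on the Paneth list and not among its 6 genes. Gsdmc2, a gasdermin of the intestinal epithelium, was higher, at 6.76 ± 2.12 against 0.12 ± 1.71 in Balb (log2 fold change 6.64, SE 1.07, limma adjusted p = 0.0169). Gsdmc3 stood at 4.37 ± 2.20 against the lowest value in all Balb libraries (limma adjusted p = 0.0364). In all, limma called 18 genes, 2 higher and 16 lower in the congenic strain, of which 7 carry predicted names. An unadjusted p under 0.05 was found for 749 genes, where 631 are to be expected by chance. The count of called genes was 11 without B6 replicate 4, Balb replicate 1 or Balb replicate 2, and 8 without congenic replicate 3 or 4. It was 5, 3 higher and 2 lower, without both Balb replicates 1 and 2, the libraries richest in Paneth and in mitochondrial transcripts, and 2 of these 5 were among the 18. The limma adjusted p rose to 0.0876 for Gsdmc2 and 0.0983 for Defa5 without congenic replicate 4, and to 0.162 for Gsdmc3 and 0.0778 for Defa3 without congenic replicate 3.

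Of 14 Paneth genes 14 were lower in the congenic strain than in Balb, with 6 falls over all genes and 11 adjusted over the list alone (camera adjusted p = 1.12e-25). This was the list that kept its call with an estimated correlation (camera adjusted p = 0.0256) and by fry (adjusted p = 0.0126). Mitochondrial genes were lower in 13 of 13, with 13 falls adjusted over the list alone and none over all genes (camera adjusted p = 5.43e-20). With an estimated correlation the mitochondrial list had a camera adjusted p = 0.143. The goblet list was lower in 12 of 12 genes, the enteroendocrine list in 5 of 6 and the stem list in 9 of 12, with none passing by either adjustment (camera adjusted p = 8.97e-05, 0.00553 and 0.0125). Their camera adjusted p were 0.432, 0.143 and 0.221 with an estimated correlation. Interferon-stimulated genes were lower in 24 of 30 and proliferation genes higher in 22 of 25, also with none passing by either adjustment (camera adjusted p = 0.000559 and 0.00279). These lists had camera adjusted p = 0.683 and 0.792 with an estimated correlation. Tuft identity genes were higher in 37 of 45 (camera adjusted p = 0.0832). With 1 library left out the camera adjusted p rose to 0.644 for interferon (Balb replicate 3), 0.778 for proliferation (Balb replicate 2), 0.0802 for enteroendocrine (Balb replicate 1) and 0.0792 for stem genes (Balb replicate 4).

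Over the 265 genes called between the parents, among them Cela2a, Cd74 and Gvin1, the congenic strain lay nearer to Balb. Its median position was 0.81 on a scale where B6 is 0 and Balb is 1 (SD 0.05 over the 4 congenic libraries), with quartiles at 0.51 and 0.99. Of the genes, 202 were nearer Balb and 63 nearer B6, among the latter Gsdmc2 (6.39 ± 1.94 in B6). Simulated libraries equal to B6 gave a median position of 0.12 and libraries equal to Balb 0.88, since the genes were chosen on the same Balb and B6 libraries. Between the congenic strain and B6 alone 126 of the 265 also passed, between the congenic strain and Balb alone 16, in both 1 and in neither 122. The genes called against B6 in both comparisons numbered 127, 52 higher and 75 lower, all in the same direction, where independent lists of these sizes would share 0.71 and 0.98. Both comparisons use the same B6 libraries, which by chance alone gave a correlation across genes of 0.499 against the observed 0.661. The covariance was 0.621 against 0.239 by chance, a difference of 0.382. With the B6 libraries split between the comparisons the correlation was 0.322 on average over 6 splits. Genes are not independent replicates in these correlations. Without Balb replicate 1 the median position was 0.70.

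**Figure D3:**
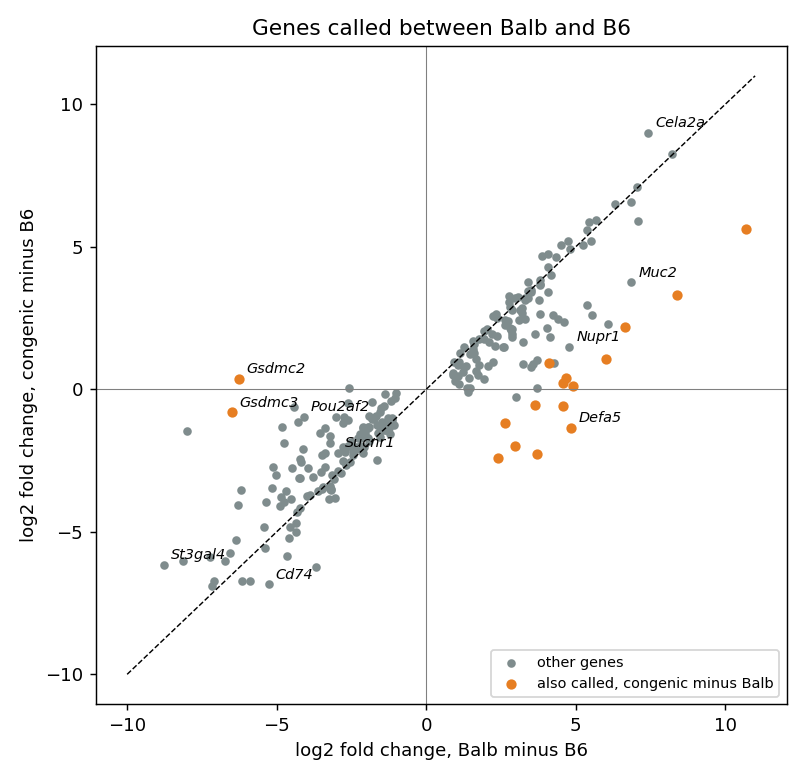
Log2 fold change of congenic minus B6 (vertical axis) against Balb minus B6 (horizontal axis) for the 265 genes called between Balb and B6 (points); the dashed line marks equal change and orange points are genes also called between the congenic strain and Balb. The median position is 0.81 (0 is B6 and 1, on the dashed line, is Balb), and both axes share the B6 libraries.

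Part of the called genes have near-identical copies, among which reads may not be assigned with certainty, so their values are uncertain as single genes. How many reads were ambiguous was not measured. A copy is here a match at 90% identity over 50% of the shorter transcript, which also joins some genes by a partial match. Cd63, Mpp7, Tfb1m and Tstd3, for example, all matched the predicted gene Gm24576, and Ocel1 matched Nr2f6. The numbers below count matches by this rule and not gene families alone. Of the 242 genes called between Balb and B6 that have a reference transcript, 69 (28.5%) had a near-identical copy in the table. They form 43 groups with overlapping copies, so genes are not independent in the tests that follow. Of 1000 sampled genes not called, 108 did (10.8%; Fisher's exact test, odds ratio 3.29, p = 5.99e-11). Between the congenic strain and B6 it was 43 of 150 (28.7%, Fisher's exact test, odds ratio 3.32, p = 3.97e-08). When each of these genes was replaced by the sum over itself and its copies, 40 of the 69 and 29 of the 43 were no longer called. The median size of the log2 fold change went from 3.79 to 1.05 and from 3.65 to 0.94. Tpm3-rs7, a copy of a tropomyosin gene, went from 5.69 (limma adjusted p = 2.1e-08) to 0.26 in Balb and from 5.94 (limma adjusted p = 1.1e-08) to 0.41 in the congenic strain. The ribosomal protein gene Rps2 went from -6.72 (limma adjusted p = 2.99e-08) to 0.28 in the congenic strain, and the sum for Hist1h2al, a histone gene listed at the lowest value in all B6 libraries, gave 0.16. Mptx1 (2.76, limma adjusted p = 0.532) and H2-K1 (-0.97 in Balb, limma adjusted p = 0.275, and -0.65 in the congenic strain, 0.673) lost their calls. The H2-K1 sums follow the more abundant H2-D1 (-0.90 and -0.56 alone) and do not decide about H2-K1 itself. The gasdermin sum reached from Gsdmc3 or Gsdmc4 kept its fall in Balb (-7.25, limma adjusted p = 0.00157), as did the sum reached from Sprr2a1 or Sprr2a2 (-7.19, limma adjusted p = 0.0012) and the Gvin1 sum (-5.88, limma adjusted p = 0.000568). Defa22 (2.97 as a single gene), 1 of the 8 Paneth rises, and Defa20 (2.39) share the sum of Defa21 and lost their calls in Balb minus B6 too (1.65, limma adjusted p = 0.306). The sum reached from Defa3 or Defa17, each with 5 copies, kept its rise (3.88, limma adjusted p = 0.00762).

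**Figure D4:**
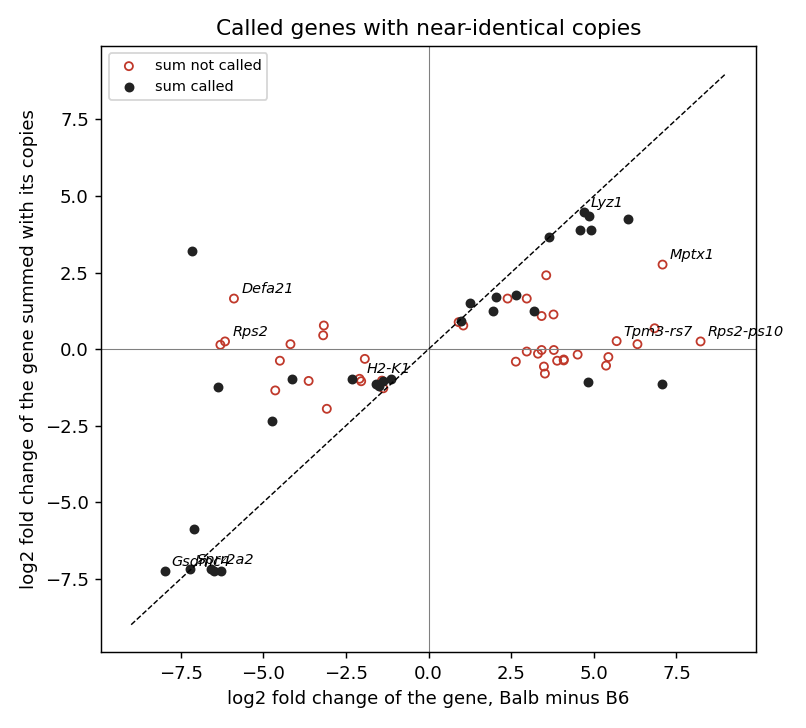
Log2 fold change of Balb minus B6 of single called genes with a near-identical copy (horizontal axis) against that of the sum over the gene and its copies (vertical axis), 69 genes; the dashed line marks equality. Genes such as Tpm3-rs7 fall close to 0 on the vertical axis, while Gsdmc4 and Sprr2a2 stay near the dashed line.

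Called genes were not concentrated on a chromosome in Balb minus B6 or congenic minus B6 by Fisher's exact test per chromosome, where limma gave 1525 and 1176 genes an unadjusted p under 0.05. For Balb minus B6, 1 chromosome passed without B6 replicate 4 and 1 without Balb replicate 2. In congenic minus Balb 7 of the 10 called genes with a known chromosome lay on chromosome 8. Only these 10 of the 18 called symbols were found in the reference annotation. They form 5 groups with overlapping copies, so they are not independent and the test is not read there.

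Summed marker transcripts, taken as a measure of the purity of the sort, differed most between groups for Paneth genes. The log2 sum was 13.09 ± 1.62 in Balb, 9.19 ± 1.02 in B6 and 9.55 ± 1.08 in the congenic strain, with all Balb libraries above all others. The exact permutation p was 0.0286 against either group, the smallest that 4 against 4 libraries allow. The goblet sum was 12.74 ± 1.95 in Balb, 9.81 ± 0.61 in B6 and 11.06 ± 2.22 in the congenic strain. The tuft identity sum was 15.19 ± 0.65, 15.55 ± 0.39 and 15.38 ± 0.38 in the same order, with exact permutation p of 0.4 for Balb against B6 and 0.543 for the congenic strain against B6. Enterocyte transcripts were also abundant, with 8750.5 to 34743 CPM per library against 20899.9 to 69957 for tuft identity. In Balb replicate 2 their sum was above that of tuft identity (34743 against 33894 CPM). Such sums are not shares of cells and do not show which cells a called gene came from. The sum of myeloid genes differed by -0.54 between the congenic strain and B6 with groups apart (exact permutation p = 0.0286). Chance separates 2.86% of comparisons of 4 against 4 libraries. Of the 39 such comparisons made none passed after adjustment (lowest adjusted exact p = 0.371). Given the smallest p that the exact test allows, many comparisons would have to reach it for any to pass.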

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

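All tests of explanations in this part were chosen after the result they measure, or the values it is made of, had been seen, except the share of calls lost on summing copies; a few pairs of copies that mirror each other, such as Rps2 and a pseudogene of it, had been seen before that one too. In 23 of 171 groups of 4 libraries examined, 1 library stood far from the other 3, where about 8.6 are to be expected by chance. That number does not allow for ties. Where 3 libraries shared the lowest value the remaining one was flagged by construction, as for Calhm3 and Cd2 in congenic replicate 3. The excess over chance therefore says little. Of the 35 splits of the 8 libraries of each comparison, 1, the real one, gave as many called genes. It gave 265 for Balb minus B6 against at most 3 in the other splits, and 160 for congenic minus B6 against at most 1. For congenic minus Balb it gave 18 against at most 4. The real split alone out of 35 is the smallest share possible, not adjusted over the 3 comparisons. Other splits also mix the groups, which raises the spread within them. Chance assignment of libraries to groups is thus less likely for these counts but not excluded.

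Genes with a near-identical copy, some of them by a partial match only, made up 28.5% of the calls between Balb and B6 that could be examined. Summing each such gene with its copies ended the call of 58.0% of the 69 genes and turned the sign of 22. The 69 genes form 43 groups with overlapping copies (in 28 groups all calls ended and in 13 none). The median size of the log2 fold change fell from 3.79 to 1.05. Reads shared between copies would give this, but so would a sum that follows its more abundant copy. Gm5575 (3.52) summed with Hspa8 (-0.81 alone) gave -0.80. The lost calls therefore do not decide whether reads were shared. A strain variant that moves Balb reads to another copy of the reference cannot be told apart from shared reads or from a difference in transcription. The congenic strain stood at a median position of 0.90 at these genes (SD 0.04 over its libraries, with 0 for B6 and 1 for Balb). A variant or a difference in transcription would both give this. The gasdermin, Sprr2a and Gvin1 sums kept their calls, and for them a difference between the strains stays open.

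The Paneth transcripts that set Balb apart from the congenic strain are the second pattern. Reads shared between defensin copies are argued against, since 6 called defensin genes summed with their copies still had a median log2 fold change of -4.58; these sums overlap and form 3 groups, that of Defa20 and Defa22 (-4.83), that of Defa3, Defa17 and Defa24 (-4.33) and that of Defa5 (-5.95), and 0 of the 3 lost their calls. A general loss of tuft cells in favour of all other cells is also argued against, because the Paneth mean rose over the enterocyte mean by 3.09 (exact permutation p = 0.0286), while the enterocyte mean differed by 0.30 (exact permutation p = 0.743). RNA or cells of Paneth origin in the Balb libraries cannot be told apart from a difference between the strains in Paneth cells or in tuft cell transcription, which was not tested and stays open: the mean of the 7 Paneth genes that are not defensins, a test first tried for the defensin copies, was 2.52 higher in Balb with overlapping groups (exact permutation p = 0.0571). The gate would leave out Paneth cells by CD25 and Siglec-F and not by EPCAM, which they carry.

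Pou2af2 at the lowest value in Balb replicates 2 and 3 is the third pattern. Low depth is argued against, since at the mean B6 level of 39.9 CPM 110.4 reads would be expected in replicate 2 and 201 in replicate 3. A lower share of tuft cells is argued against too, because the mean of 45 tuft identity genes differed from the B6 mean by -0.72 in replicate 2 and -0.19 in replicate 3, with an SD of 0.38 over B6. A strain variant that keeps Balb reads from the reference transcript may play a part, but it cannot be told apart from a difference in transcription: the lowest congenic library was -0.98 from the highest Balb library, so the groups overlapped, and the other 2 Balb libraries were measured at 4.09 and 2.77. A difference between the strains in transcription of the gene stays open and untested. Balb is an inbred strain, so a variant or a strain difference would be shared by all Balb libraries. Neither accounts by itself for the split of replicates 2 and 3 from the other 2, whose cause was not tested.

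Balb replicate 1 stood apart as the highest of its group in the log2 Paneth sum (15.52), Defa5 (11.08), Defa20 (9.65), Itln1 (12.13), St3gal4 (1.5), Sprr2a1 (-0.09) and Gvin1 (-0.96). Balb replicate 2 stood apart in its summed CPM (1474.6 in units of 1e3 CPM). In Balb replicate 3 Gsdmc4 was highest (2.24) and Muc2 lowest (4.10), and in Balb replicate 4 Hist1h2al was lowest (3.02). In congenic replicate 3 Cd74 (2.48), Calhm3 (1.06) and Cd2 (0.70) were highest, in congenic replicate 1 Defa17 was highest (7.68) and B2m lowest (9.72), and in congenic replicate 4 Cela2a was lowest (7.06). In B6 replicate 4 Ceacam10 (1.87) and Defa-rs7 (1.13) were highest, in replicate 1 Sucnr1 (10.21) and Fah (-0.14), in replicate 2 Slc12a2 (6.65) and in replicate 3 Cela2a (-0.59).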

How the results depend on the processing

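Pseudocount 1 CPM, leaving out Balb replicates 1 and 2 together, leaving out predicted names, summing copies and fry's test of change in either direction were chosen after seeing the data; all other settings were planned. Summing copies reversed Defa21 in Balb minus B6 (1.65) and Rps2 in congenic minus B6 (0.28), since it adds the copies' own values. Outside the rule for named genes it also turned Rps2 (0.25) and Hist1h2al (-0.54) in Balb minus B6 and Gm7293 in both comparisons with B6 (-1.08 and -1.03). No other called gene that the rule names in a comparison changed sign there in any setting run. With 1 library left out 265 of 312 values of called genes kept their call in Balb minus B6, 224 of 264 in congenic minus B6 and 75 of 96 in congenic minus Balb, the others weakening; in other settings 283 of 320, 255 of 271 and 85 of 103 kept it.

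Called genes in Balb minus B6 (265) numbered 174 to 271 with 1 library left out (lowest without B6 replicate 1) and 175 without Balb replicates 1 and 2, of which 139 were shared with the 265; the percent of higher calls went from 48.3 to 38.3 without Balb replicate 1 and to 38.9 without both. In congenic minus B6 (160) they numbered 96 to 170 with 1 left out (lowest without congenic replicate 2, and 104 without B6 replicate 2) and 258 with quality weights. In congenic minus Balb (18) they numbered 8 to 23 with 1 left out (8 without congenic replicate 3 or 4; 11 without B6 replicate 4, Balb replicate 1 or Balb replicate 2), 5 with no variance trend, 5 without Balb replicates 1 and 2 (3 higher and 2 lower against 2 and 16, with 2 shared with the 18), and 11 without predicted names, since fewer genes were counted.

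Called lists in Balb minus B6 (11) numbered 0 with an estimated correlation and 0 with fry, and 5 to 11 with 1 library left out (5 without Balb replicate 4, 7 without Balb replicate 1). In congenic minus B6 (8) they numbered 0 and 0, and 3 to 10 (3 without congenic replicate 2, 5 without B6 replicate 2); in congenic minus Balb (7) 1 and 1, the Paneth list. These fry counts are for genes that move, on balance, in 1 direction. By fry's test of change in either direction 9, 5 and 3 lists passed in the order of comparisons above. Of these, 5, 1 and 3 were also called by camera. Known strain differences passed in congenic minus B6 too (fry adjusted p = 0.00148). There 3 of its genes fell and 1 rose adjusted over the list alone, and 0 passed over all genes. Neither fry test compares a list with other genes.

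Pou2af2 in Balb minus B6 kept its direction and lost its call with pseudocount 0.25 CPM (-4.43, limma adjusted p = 0.0574), only the 2 groups compared (-4.09, limma adjusted p = 0.12), no variance trend (-4.09, limma adjusted p = 0.114) and a robust prior (-4.09, limma adjusted p = 0.0501); with 1 library left out it ranged from -5.11 to -3.30. The congenic position was 0.73 without Balb replicates 1 and 2 and 0.70 (without Balb replicate 1) to 0.88 (without B6 replicate 1) with 1 left out. Chromosomes passing for Balb minus B6 numbered 0 to 1 (1 without B6 replicate 4 or Balb replicate 2). Marker sums with groups apart numbered 1 per comparison; means of log2 values gave 4 for Balb minus B6 (Paneth, goblet, T cell and eosinophil) and 0 for congenic minus B6, and leaving out 1 library gave 1 to 3, 1 to 4 and 1 to 2 in the order of comparisons above, where smaller groups separate more often by chance. For the changes in this part not explained by their construction, the cause was not tested.

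The low-value filter and its removal changed nothing, since 0 genes were removed, and count models were not run, since whole reads could not be recovered. No paired analysis was possible because the labels carry no replicate numbers that pair libraries. Depth limits mainly genes near the lowest value, of which 415 to 1309 per library were listed at it.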

Other observations

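The genes and all tests of this part were chosen after their values were seen. Arntl, the core activator of the circadian clock, stood at 3.82 ± 0.98 in B6 and -0.99 ± 0.68 in Balb (log2 fold change -4.81, SE 0.82, limma adjusted p = 0.00317) and at 2.50 ± 1.51 in the congenic strain (-1.32 against B6, limma adjusted p = 0.71), and Bhlhe41, a repressor of the clock, rose by 1.47 in Balb (limma adjusted p = 0.0271) and differed by 0.06 in the congenic strain. Per1, Per2, Cry1, Nr1d1 and Dbp, other genes of the clock, did not pass in either comparison. Nupr1, a stress-response gene, rose from 0.89 ± 0.95 in B6 to 5.67 ± 0.61 in Balb (limma adjusted p = 0.000562), with 2.38 ± 1.04 in the congenic strain, and Bhlha15, a transcription factor of secretory cells, stood at -1.05 ± 0.33, 1.97 ± 0.88 and the lowest value in all congenic libraries (limma adjusted p = 0.0155 for Balb minus B6). The Paneth transcripts were higher in Balb too.

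Among further genes, Gcnt1, which branches O-glycans, fell by 5.37 in Balb (SE 0.72, limma adjusted p = 0.000489) and by 3.95 in the congenic strain (limma adjusted p = 0.00768), and B3gnt3 stood at 4.18 ± 0.55 in B6, 1.79 ± 0.91 in Balb and 0.82 ± 1.32 in the congenic strain, called in the last alone (limma adjusted p = 0.0327). Galnt12, which starts O-glycans, rose by 3.13 in Balb (limma adjusted p = 0.0408), and Chst4, a sulfotransferase, stood at 3.28 ± 1.23 in Balb and at the lowest value in all B6 libraries (limma adjusted p = 0.00965). Genes called against B6 in both strains included Alad, an enzyme of haem synthesis (6.16 ± 0.40 in B6, 8.11 ± 0.39 in Balb and 8.19 ± 0.17 in the congenic strain), and the actin regulator Cap1 (4.60 ± 0.90, 7.35 ± 0.54 and 7.86 ± 0.23). The ectoenzyme gene Cd38, also called in both, stood at 7.92 ± 0.36, 5.72 ± 0.29 and 6.21 ± 0.09. All congenic libraries lay above all Balb libraries, but congenic minus Balb was not called (0.49, limma adjusted p = 0.846). The gasdermin gene Gsdmc2 instead stood at 6.39 ± 1.94 in B6, 6.76 ± 2.12 in the congenic strain and 0.12 ± 1.71 in Balb, and Gsdmcl2 at 3.42 ± 1.09, 1.55 ± 2.44 and the lowest value in all Balb libraries.

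Pou2af2 lay nearer to B6 than to Balb in the congenic strain, and 1 hypothesis is that the strain carries B6-like expression in a stretch of chromosome 9 around the gene. The test did not decide and the hypothesis stays open. Of the 100 tested genes nearest in order to Pou2af2, 7 had an unadjusted limma p under 0.05 between Balb and B6. By chance 5 are to be expected (exact binomial test, one-sided p = 0.234), while over all genes 1525 of 12614 had such a p. The 7 neighbours had a median position of 0.78 (0 for B6 and 1 for Balb), and 1 of them lay under 0.5. In single congenic libraries this median was 0.57 to 0.76 (SD 0.08). Of 9671 windows of 100 tested genes, 82.7% had a median position as low or lower. With no excess of such genes over the genome, the position says little about the stretch. The neighbour with the lowest p, Gm7293, went from 4.82 in Balb minus B6 to -1.08 when summed with its near-identical copies.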
